A study of Rattus norvegicus with 12 samples.

How the data were processed

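Total RNA was extracted with Trizol from N27 cells exposed to 25 µM fipronil for 24 h (6 samples) and from untreated cells (6 samples), labelled with Cy3 and hybridised to Agilent one-colour rat arrays. The treatment of each sample was taken from its title and treatment label. Each array carried 62976 spots, of which 58717 were not controls and represented 45598 probes. The labels do not say whether the replicates of a group come from separate cultures, so every p-value measures the spread between these samples, which may be technical. Nor do they say whether control cells received a vehicle, so a difference may include an effect of one. The number of arrays, 6 in each group, limits the precision.

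Spots were quantified by the authors with Agilent Feature Extraction (version 10.7 per the submitters' processing notes). Per the file headers, the processed signal of each array is a background-subtracted and detrended intensity with no scaling between arrays, and the mean signal and local background median are raw intensity values. Per the file headers, the remaining columns used are flags, other values of 0 or 1 set by the extraction software: well above background, saturated, and outlier. The deposited table of the series holds log2 values that the authors quantile-normalized over the 12 arrays, with the lowest values set to 1.5. Each of its columns had a median of 2.63, and the values were not centred. Each column of that table was checked against the processed signal of its own array (correlation at least 0.9999), and no other array matched it as closely.

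The processed signals were used for the comparisons. Spots marked as outliers by the software (323 to 711 spots per array) were left out unless every spot of the probe was marked. Of the spots that were not controls, 0 were saturated. Values were converted to log2, the 75th percentile of each array's spots that were not controls was subtracted, and replicate spots of a probe were then averaged. A probe was kept when it stood well above background on at least 6 of the 12 arrays, counted without regard to treatment, which left 16291 probes. For each gene the probe with the highest mean signal was used, giving 13542 genes and transcripts, 9540 of them with a gene symbol. Current names were taken from a RefSeq annotation of the rat assembly GRCr8, by accession for 21109 probes, by symbol for 6684 and by synonym for 424, and 17381 probes kept the name in the files. The array files place probes on an older assembly, so chromosomes are given from the annotation and no coordinates are printed.

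Fipronil and control arrays were compared gene by gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with version 1.17.8 of the data.table package, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Slide was not a term of this fit, because slide 2 holds controls alone and slide 3 fipronil arrays alone. A fit with slide as a fixed block takes its treatment difference from slide 1, which holds 2 arrays of each treatment. Replicate numbers 2, 3, 7 and 8 occur in both groups. The deviations of same-numbered arrays correlated at 0.43, 0.08, -0.11 and -0.31 over genes, which are not independent replicates. Same-numbered arrays lie on different slides, so these values cannot decide whether the numbers mark pairs. The numbers were not used as pairs. A fit with the number as a block was kept as an alternative.

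Before the data were examined, 37 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The 32 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera ranks a list against all other tested genes, so its direction can differ in sign from the list's median. Named genes were the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05, no overlap between groups and the same direction on slide 1. They also included, for each list, up to 4 members past the threshold with the smallest adjusted p, or the 2 members with the highest signal where none passed. Th, Slc6a3, Cyp1a1, Hmox1, Ddit3 and Cdkn1a were named whatever their values. The rule gave 103 genes, some of which are not reported here, and of the others 95 were tested and 61 passed. Genes named outside it are marked as chosen after their values were seen. A fold for a gene with no array of 1 group well above background was computed against a background level. That level was the lowest value called well above background on each array, and values under it were raised to it. Values above it were left as measured, so such a fold is not a strict bound. A difference on slide 1 was treated alike for a gene with no array of 1 group well above background there.

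The alternatives were quantile normalization, median scaling, a normexp background (offset 50) followed by quantile or 75th percentile scaling, and the deposited log2 values. Others changed the filter (none, or well above background on all 12 arrays) or the probes (mean of a gene's probes, or every probe). Further fits used slide as a fixed or random block, slide 1 alone, slides 2 and 3 alone, the replicate number as a block with and without slide, eBayes with trend and robust settings, array weights, and each array left out in turn. Removal of each array's trend over probe GC content (loess span 0.4), with and without slide as a block, and a fit without the 4 arrays of slide 3 were added after seeing the data.

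The procedure was tested on simulated data with 200 changed genes among 13542 in 5 simulations. It recovered 20.0% of changes of 0.5, 71.3% of changes of 1 and 96.4% of changes of 2 on the log2 scale, and 3.53% of its calls were false. A list shifted by 0.5 was called in 5 of 5 simulations with 0 of the other lists. These rates describe the simulated data. They were not tested for arrays with a slide structure or for lists of correlated genes. In the real arrays the estimated correlation within a list reached 0.73, for ATF4 targets, against the preset 0.01. Of 100 splits of the real arrays, the real one included, 43 reached 8 called lists. The simulated rate for lists therefore does not carry over to these arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.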

Results

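Transcript levels were measured on one-colour microarrays in N27 cells, a rat dopaminergic neural cell line. Total RNA from 6 samples of cells exposed to 25 µM fipronil for 24 h was compared with total RNA from 6 untreated control samples. Fipronil is a phenylpyrazole insecticide that blocks chloride channels gated by GABA. The question put by the study's title was which effects the pesticide has in these cells.

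The 12 arrays lay on 3 slides. Slide 1 held control replicates 2 and 3 and fipronil replicates 7 and 8. Slide 2 held control replicates 5 to 8 alone, and slide 3 held fipronil replicates 1 to 4 alone. The 75th percentile of the processed signal averaged 260 ± 16.9 (SD, n = 4) on slide 1, 436 ± 43.5 (SD, n = 4) on slide 2 and 126 ± 15.2 (SD, n = 4) on slide 3. Between 44.5% and 46.8% of the spots on slide 1 stood well above background. The shares were 47.4% to 50.02% on slide 2 and 40.8% to 42.5% on slide 3. On the slide with both treatments the percentile was 269 and 279 in the control arrays and 246 and 245 in the fipronil arrays.

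**Figure D1:**
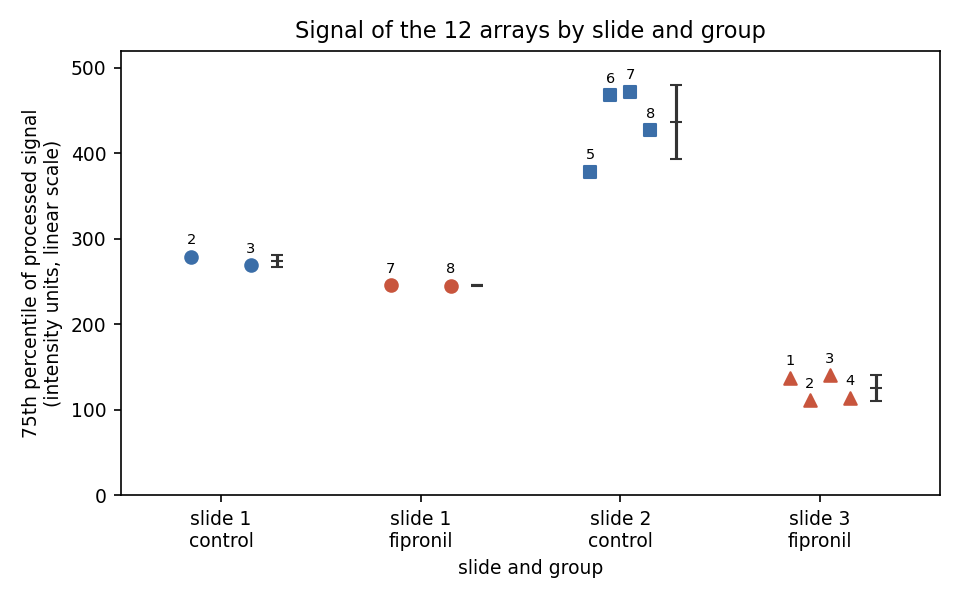
The 75th percentile of the processed signal (intensity units) is plotted for each of the 12 arrays, grouped by slide and coloured by treatment. Bars beside the points give the mean and SD. The 4 arrays of slide 3, all fipronil, lie between 111 and 140, and the 4 arrays of slide 2, all control, lie between 379 and 472.

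After 24 h of fipronil, the lysosomal enzyme acid alpha-glucosidase (Gaa) rose 2.17-fold, and the gene Rn5-8s, which encodes a ribosomal RNA, rose 3.26-fold. The Wnt pathway component beta-catenin (Ctnnb1) fell 2.07-fold, arginase (Arg1) fell 2.36-fold, and Txnip, an inhibitor of thioredoxin, fell 2.5-fold. Transcripts of single members of several pathways moved with them. Lanosterol synthase (Lss) rose 1.97-fold, the clock output factor Dbp rose 1.87-fold, the proto-oncogene Myc fell 1.81-fold and the chemokine Cxcl2 fell 1.91-fold. Each fold compares 6 fipronil with 6 control arrays, and slide and treatment nearly coincide. When slide was a fixed block, of these 9 genes Gaa alone stayed past the threshold, and the adjusted p of the others ran from 0.0952 for Rn5-8s to 0.468 for Cxcl2.

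Of 13542 genes and transcripts tested with limma, 678 passed an adjusted p of 0.05, 303 higher and 375 lower with fipronil. Which direction held more genes depended on the processing, with 150 higher and 435 lower under median scaling and 498 and 337 with the GC trend removed. Of these 678, 516 carried a gene symbol, 48 rose and 46 fell at least 2-fold, and 412 had no overlap between the fipronil and control values. Chance gives no overlap in 0.216% of genes, and 4.18% of the tested genes had none. The chance value treats the 12 arrays as exchangeable, although slide and treatment nearly coincide, so the excess cannot be told apart from slide. With slide as a fixed block, which takes the treatment difference from slide 1 alone, 12 genes passed, 3 of them among the 678: Gaa, and Gpnmb and Tecpr1, which were named after their values were seen. With slide as a random block 21 passed, all among the 678.

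The 12 largest rises among genes with a symbol, no overlap and the same direction on slide 1 were those of Rn5-8s, Ttll7, Morc4, Sync, Eppk1, Or51i2, Taok3, Peak1, Ppfia1, Gaa, C8g and Tenm4. Their folds ran from 2.08 for the teneurin Tenm4 to 3.26 for Rn5-8s. The log2 signal of Rn5-8s, relative to each array's 75th percentile, was 1.23 ± 0.38 (SD, n = 6) in controls and 2.94 ± 0.51 (SD, n = 6) with fipronil. Its log2 difference was 1.70 ± 0.24 (SE), with an adjusted p of 0.00551, and was 1.62 on slide 1. The log2 signal of Gaa, on chromosome 10, was -0.67 ± 0.29 (SD, n = 6) in controls and 0.44 ± 0.23 (SD, n = 6) with fipronil. Gaa differed by 1.12 ± 0.15 (SE) on the log2 scale over the 12 arrays (adjusted p 0.00551) and by 1.59 ± 0.20 (SE) with slide as a fixed block (adjusted p 0.0222, and 0.00069 to 0.266 over the alternatives). Peak1, which encodes a pseudokinase of the cytoskeleton, rose 2.21-fold (log2 difference 1.15 ± 0.16 SE, adjusted p 0.00551, and 0.70 on slide 1). Ttll7, a tubulin polyglutamylase, rose 2.81-fold and the scaffold protein gene Ppfia1 rose 2.17-fold, with log2 differences of 0.76 and 0.60 on slide 1. The complement gene C8g rose 2.14-fold and the cytolinker gene Eppk1 2.31-fold, with log2 differences of 1.40 and 1.60 on slide 1. Taok3 was past the threshold in 4 of the 12 fits that left out 1 array, and the other 11 rises were past it in all 12 fits. When a probe had to be well above background on all 12 arrays, 9 of the 12 rises could be tested, and all 9 passed. Ttll7, Or51i2 and Taok3 could not be tested there, so their folds rest partly on values not well above background.

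The largest falls by the same rule included those of 11 genes: Nt5c1b, Trim21, Slc26a4, Lemd3, Txnip, Lrp12, Arg1, Stam, Ccdc103, Bdnf and Ctnnb1. For Nt5c1b, Trim21, Slc26a4, Stam and Ccdc103 no fipronil array stood well above background, so their falls are given against the background level and are not strict bounds. Against that level the nucleotidase Nt5c1b was 2.67-fold lower, the ubiquitin ligase Trim21 2.0-fold and the anion exchanger Slc26a4 1.90-fold. The endosomal adaptor Stam was 1.49-fold lower and Ccdc103 1.36-fold. The log2 signal of Ctnnb1 was -1.56 ± 0.17 (SD, n = 6) in controls and -2.61 ± 0.28 (SD, n = 6) with fipronil. Ctnnb1 fell by 1.05 ± 0.14 (SE) on the log2 scale (adjusted p 0.00551), and its difference on slide 1 was -0.63. Arg1 differed by -1.24 ± 0.23 (SE, adjusted p 0.0154), with -1.23 on slide 1 and -1.25 across slides 2 and 3. Txnip differed by -1.32 ± 0.24 (SE, adjusted p 0.0154), with -0.56 on slide 1 and -1.70 across slides 2 and 3. The neurotrophin Bdnf fell 2.10-fold, with 1 fipronil array well above background. The nuclear membrane protein gene Lemd3 fell 2.72-fold, also with 1 such array, and Lrp12 fell 2.39-fold with 2. The folds of Bdnf, Lemd3 and Lrp12 thus rest mostly on fipronil values not well above background, and they were not computed against the background level. Bdnf was past the threshold in 4 and Ccdc103 in 2 of the 12 fits that left out 1 array, and the other 9 of these falls in all 12.

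All 12 rises kept their direction under the 5 other scalings, whereas 8 of these 11 falls turned to rises with a normexp background and 75th percentile scaling, where the median of all genes was 0.17, Txnip, Arg1 and Ctnnb1 being the exceptions. The count of changed genes was 228 without fipronil replicate 3 and 2022 without fipronil replicate 8, and without any 1 of the other arrays except fipronil replicate 7 it lay between 242 and 395.

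**Figure D2:**
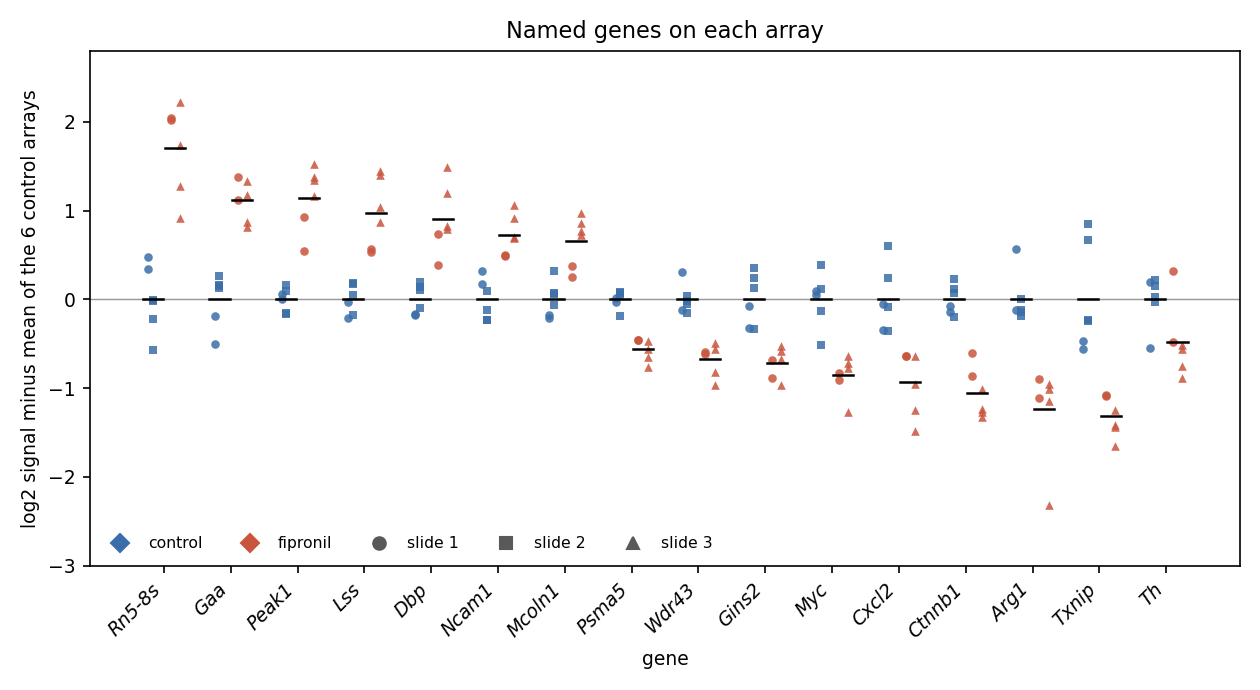
For 16 genes, each point gives the log2 signal of 1 array minus the mean of the 6 control arrays, with colour for treatment, marker shape for slide and a bar at the group mean. Rn5-8s, Gaa, Peak1, Lss and Dbp show no overlap between the 6 fipronil and 6 control values, and the values of Th overlap.

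Marker transcripts of dopaminergic neurons did not pass the threshold over all genes. Tyrosine hydroxylase (Th), which catalyses the rate-limiting step of dopamine synthesis, had a log2 signal of -1.37 ± 0.29 (SD, n = 6) in controls and -1.86 ± 0.42 (SD, n = 6) with fipronil. The log2 difference of Th was -0.48 ± 0.20 (SE, adjusted p 0.152), with 0.10 on slide 1 and -0.77 across slides 2 and 3. The dopamine transporter gene Slc6a3, with 2 probes, and the dioxin-responsive Cyp1a1, with 1 probe, stood well above background on 0 of 12 arrays and were not tested. Of 6 tested dopaminergic markers 0 passed over all genes in limma, with 2 at an unadjusted p under 0.05, and 1, Aldh1a1, was lower when adjusted over the list alone (log2 difference -0.84, adjusted p 0.0678 over all genes and 0.0338 adjusted over the list alone). Of 7 neuronal and synaptic markers 1 rose, the adhesion molecule Ncam1 (1.66-fold, log2 difference 0.73 ± 0.14 SE, adjusted p 0.0171, 0.25 on slide 1). The syntaxin Stx1a also passed when adjusted over the list alone (2 genes).

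Fipronil's known target family was sparsely detected, with 5 of 32 listed genes for GABA receptors, glycine receptors and GABA handling tested. The glycine receptor subunit Glra1 fell 2.21-fold (log2 difference -1.15 ± 0.28 SE, adjusted p 0.0349, -0.35 on slide 1), with 1 fipronil array well above background, and turned to a rise with a normexp background and 75th percentile scaling. Gabrq was lower as well when adjusted over the list alone (2 genes), with a log2 difference of -0.64 and an adjusted p of 0.125 over all genes. The list was not shifted (median log2 difference 0.03, mean -0.27, camera adjusted p 0.736). For markers of other cell types, 3 astrocyte, 3 oligodendrocyte, 3 microglia and leukocyte and 2 endothelial genes were tested, too few for a list test. In limma 0 of these passed over all genes, with 0, 2, 1 and 1 of them at an unadjusted p under 0.05. Among these genes, Aldoc differed by -0.19 and Sox9 by 0.28, Cnp by -0.53 and Mag by -0.69, Cx3cr1 by 0.27 and Cd14 by -0.38, and Vwf by -0.04 and Flt1 by 0.69 on the log2 scale. Their adjusted p ran from 0.0707 for Flt1 to 0.881 for Vwf. Mag was lower and Flt1 higher when adjusted over the list alone.

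The S phase and DNA replication list of 36 tested genes was shifted lower, with a median log2 difference of -0.32 (camera adjusted p 0.0022). Its adjusted p = 0.647 with an estimated correlation. The replication initiation factor Gins2 fell 1.65-fold (log2 difference -0.72 ± 0.14 SE, adjusted p 0.0187, -0.59 on slide 1) and the polymerase clamp Pcna fell 1.31-fold (-0.39 ± 0.10 SE, adjusted p 0.0467, -0.49 on slide 1). Pcna was past the threshold in 1 of the 12 fits that left out 1 array. Over all genes 2 members fell, and adjusted over the list alone 13 fell. On slide 1 the list's median was -0.16, with 12 of 36 members higher, and its adjusted p with slide as a fixed block was 0.202, against 7.1e-12 to 0.647 over the alternatives. The G2 and M phase list was not shifted (median -0.01, mean 0.07, adjusted p 0.153), although Nusap1 rose 1.46-fold (0.22 on slide 1) and Prc1 1.49-fold. Prc1 had a log2 difference of -0.0048 on slide 1 and 0.87 across slides 2 and 3. On slide 1 the G2 and M phase list was lower (median -0.19, 5 of 34 members higher, adjusted p 0.0252 with slide as a fixed block, and 0.811 with an estimated correlation as well).

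The proteasome list was shifted lower both over the 12 arrays and on slide 1. The median log2 difference of 31 tested subunits was -0.21 (camera adjusted p 0.0199) over all arrays. The adjusted p = 0.647 with an estimated correlation. Within slide 1 the median was -0.26, with 3 of 31 members higher, and the call held with slide as a fixed block (adjusted p 0.0011, and 3.52e-11 to 0.647 over the alternatives), but not with an estimated correlation as well (adjusted p 0.811). The core particle genes Psma5, Psma1 and Psmb3 fell 1.47-fold, 1.36-fold and 1.48-fold, and Psmd14, of the regulatory particle, fell 1.41-fold, with -0.45, -0.45, -0.26 and -0.71 on slide 1. Psma5 had an adjusted p of 0.0135 and a log2 difference of -0.56 ± 0.10 (SE). Over all genes 4 members fell, and adjusted over the list alone 6 fell. The call was lost without control replicate 5 or fipronil replicate 7 or 8, with adjusted p from 0.0559 to 0.131, and with the GC trend removed (0.0521).

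The immediate early gene list was shifted lower as well, with a median of -0.25 over 16 genes (camera adjusted p 0.0499). The adjusted p = 0.647 with an estimated correlation. On slide 1 the median was -0.33, 1 of 16 members was higher, and the adjusted p with slide as a fixed block was 0.0295, against 4.36e-05 to 0.647 over the alternatives. In the slide-blocked fit it was 0.811 with an estimated correlation and 0.091 with the GC trend removed. Myc fell 1.81-fold (log2 difference -0.86 ± 0.16 SE, adjusted p 0.0153, -0.94 on slide 1), Junb 1.66-fold and the survival factor Ier3 1.57-fold (-0.21 and -0.32 on slide 1). Over all genes 3 members fell, and adjusted over the list alone 4 fell, Dusp5 being the fourth. The call was lost without control replicate 2 or 7 or fipronil replicate 3, 4, 7 or 8, with adjusted p from 0.0516 to 0.15. The ribosome biogenesis and MYC target list was not shifted over the 12 arrays (median -0.18, adjusted p 0.127), but was lower on slide 1 (median -0.52, 4 of 26 members higher, adjusted p 0.000224 with slide as a fixed block, and 0.811 with an estimated correlation as well). Of its members, Myc, the nucleolar protein gene Wdr43 (1.60-fold, adjusted p 0.0135, log2 difference -0.70 on slide 1) and Nolc1 (1.53-fold, adjusted p 0.0329, -0.84 on slide 1) fell. Of 26 members, 4 fell and 1, Dkc1, rose when adjusted over the list alone. Nop58 and Gnl3, chosen after their values were seen, differed by -1.37 and -1.28 on slide 1 and by 0.59 and 0.89 across slides 2 and 3.

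The inflammation and NF-kB target list was shifted lower over the 12 arrays, with a median of -0.29 over 23 genes (camera adjusted p 0.0303). The adjusted p = 0.647 with an estimated correlation. The chemokines Cxcl2 and Cxcl3 fell 1.91-fold and 1.85-fold and Nfkbiz 1.5-fold (-0.91 for Cxcl3 and -0.97 for Nfkbiz on slide 1). Cxcl2 had a log2 difference of -0.93 ± 0.20 (SE, adjusted p 0.0232), and -0.44 on slide 1. Over all genes 3 members fell, and adjusted over the list alone 4. On slide 1, however, the list's median was 0.27, with 14 of 23 members higher (adjusted p 0.473 with slide as a fixed block, and 9.89e-07 to 0.647 over the alternatives). Relative to the control mean, its median there was -0.23 in fipronil replicate 7 and 0.03 in fipronil replicate 8. In control replicates 3 and 2 it was -0.21 and -0.24, so fipronil replicate 8 alone stood higher. The call was lost without control replicate 5 (adjusted p 0.0654). The interferon list was not shifted (median -0.10, adjusted p 0.239), with Irf1 (1.71-fold) and B2m (1.43-fold) lower both over all genes and adjusted over the list alone. Irf1 differed by -0.13 on slide 1 and -1.09 across slides 2 and 3, and B2m by -0.38 and -0.58. On slide 1 the interferon list was higher (median 0.27, 18 of 23 members, adjusted p 0.0042 with slide as a fixed block, and 0.811 with an estimated correlation as well).

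The extracellular matrix and TGF-beta target list of 17 tested genes was shifted higher, with a median of 0.26 (camera adjusted p 0.00241). The adjusted p = 0.447 with an estimated correlation. The collagen cross-linking enzyme Loxl2 rose 1.91-fold (log2 difference 0.93 ± 0.19 SE, adjusted p 0.019), the collagen Col1a1 1.97-fold and the actin-binding protein gene Tagln 1.46-fold. On slide 1 these differed by 0.25, 0.09 and 0.81, and Col1a1 was past the threshold in 2 of the 12 fits that left out 1 array. Over all genes 5 rose and 1 fell, the protease inhibitor Timp1, and adjusted over the list alone 7 rose and 1 fell. Within slide 1 the median was 0.04, with 10 of 17 members higher, and the adjusted p with slide as a fixed block was 0.523, against 0.000896 to 0.642 over the alternatives.

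The circadian clock list was shifted higher too, with a median of 0.37 over 11 genes (camera adjusted p 0.0499). The adjusted p = 0.397 with an estimated correlation. Dbp rose 1.87-fold (log2 difference 0.91 ± 0.17 SE, adjusted p 0.0154, 0.73 on slide 1). Adjusted over the list alone 4 rose (Dbp, Cry1, Per1 and Tef) and 2 fell (Bmal1 and Nfil3). The list's median on slide 1 was 0.18, with 7 of 11 members higher (adjusted p 0.581 with slide as a fixed block, and 0.0289 to 0.581 over the alternatives). The call was lost without control replicate 3, 5 or 8 or fipronil replicate 1, 3, 4 or 8, with adjusted p from 0.051 to 0.088, and with the GC trend removed (0.0639).

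The list of mitochondrial biogenesis, dynamics and mitophagy was shifted lower, with a median of -0.27 over 20 genes (camera adjusted p 0.0199). The adjusted p = 0.397 with an estimated correlation. The fission factor Fis1 fell 1.36-fold (log2 difference -0.45 ± 0.12 SE, adjusted p 0.0479, -0.12 on slide 1), the single member past the threshold over all genes. Adjusted over the list alone 5 fell, adding Bnip3l, Mff, Opa1 and the mitochondrial transcription factor Tfam, whose log2 difference was -0.44. The median within slide 1 was -0.13, and the adjusted p with slide as a fixed block was 0.298, against 3.46e-06 to 0.397 over the alternatives. Respiratory chain genes were not shifted, with medians of -0.03 over 35 complex I subunits (adjusted p 0.849) and -0.13 over 39 subunits of complexes II to V (adjusted p 0.197). In these lists 0 members passed in limma, either over all genes or adjusted over the list alone, with 7 and 9 at an unadjusted p under 0.05. Ndufb8 differed by -0.43 and Ndufa5 by -0.29, and Cox6a1 by 0.93 ± 0.78 (SE), since its signal in control replicate 3 lay at 1.37 while the other controls lay at 6.59 to 6.95. Atp5f1a differed by -0.11. The mitochondrial unfolded protein response list was not shifted either (median 0.04, adjusted p 0.392), with Hspe1 at 0.14 and Hspd1 at 0.35, 0 members past the threshold over all genes (5 at an unadjusted p under 0.05), and 2 higher and 1 lower adjusted over the list alone.

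The apoptosis machinery list was shifted lower, with a median of -0.28 over 29 genes (camera adjusted p 0.0303). The adjusted p = 0.647 with an estimated correlation. The single member past the threshold, over all genes and adjusted over the list alone, rose: the apoptosome component Apaf1, 2.07-fold (log2 difference 1.05 ± 0.27 SE, adjusted p 0.04, 0.33 on slide 1). The median within slide 1 was 0.10, with 18 of 29 members higher (adjusted p 0.473 with slide as a fixed block, and 4.01e-08 to 0.801 over the alternatives). The call was lost without control replicate 5 or fipronil replicate 1 or 4, with adjusted p from 0.0506 to 0.0654. The p53 target list was not shifted by camera (median -0.20, adjusted p 0.48) but was called lower by fry (adjusted p 0.028), and 0 of its 20 members passed in limma, over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05. Its cell cycle inhibitor Cdkn1a differed by -0.28 (adjusted p 0.403), Bax by -0.33 and Gadd45a by -0.07. On slide 1 these differences were 0.59, 0.22 and -0.51, and across slides 2 and 3 they were -0.71, -0.60 and 0.16.

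Stress response lists were not shifted over the 12 arrays. Of 32 tested ATF4 targets 0 passed in limma, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05 (median -0.08, mean -0.03, camera direction up relative to other genes, adjusted p 0.848). The stress factor Ddit3 differed by 0.73 ± 0.33 (SE, adjusted p 0.189), Gars1 by 0.53 and Phgdh by 0.13. On slide 1 the ATF4 list was higher, with a median of 0.40 and 28 of 32 members up (adjusted p 0.0011 with slide as a fixed block, and 0.811 with an estimated correlation as well). Across slides 2 and 3 its median was -0.34, but the slide 2 controls were split. Relative to the control mean, the list's median was 0.70 and 0.73 in control replicates 5 and 6. It was -0.27 and -0.33 in control replicates 7 and 8. In fipronil replicates 1 to 4 of slide 3 it was -0.39, -0.40, 0.27 and 0.07, and in fipronil replicates 7 and 8 of slide 1 it was 0.06 and 0.20. In the ER unfolded protein response list (median -0.04, mean -0.02, camera direction up, adjusted p 0.62) Atf6 rose 1.49-fold and the chaperone Dnajb11 fell 1.44-fold (0.35 and -0.26 on slide 1), over all genes and adjusted over the list alone. Hsp90ab1 rose 1.60-fold (0.37 on slide 1) in the heat shock list, alone by either adjustment (median 0.08, adjusted p 0.0887). Among 23 Nrf2 targets (median -0.0039, mean 0.03, adjusted p 0.425) the exporter Abcc1 rose 1.75-fold (log2 difference 0.81, with 0.13 on slide 1 and 1.15 across slides 2 and 3), and adjusted over the list alone 2 rose and 1, Prdx1, fell. Haem oxygenase (Hmox1) differed by 0.12 (adjusted p 0.651). Of 8 metallothionein and metal response genes 0 passed by either adjustment, with 2 at an unadjusted p under 0.05 (median -0.10, adjusted p 0.769), with Mt1 at 0.40 and Mt2A at 0.18.

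Of 28 tested autophagy and lysosome genes 2 rose and 0 fell, the lysosomal channel Mcoln1 (1.58-fold, log2 difference 0.66 ± 0.15 SE, adjusted p 0.027, 0.51 on slide 1) and cathepsin B (Ctsb, 1.33-fold, 0.41 ± 0.10 SE, adjusted p 0.0307, 0.56 on slide 1). Adjusted over the list alone 4 rose, Lamp2 among them. The list was not shifted over the 12 arrays (median 0.04, adjusted p 0.127). On slide 1 it was higher, with a median of 0.39 and 21 of 28 members up (adjusted p 0.000235 with slide as a fixed block, and 0.42 with an estimated correlation as well). The LXR target list was not shifted over the 12 arrays either (median 0.05, adjusted p 0.48), and on slide 1 all 10 members were higher (median 0.50, adjusted p 0.000435 with slide as a fixed block, and 0.42 with an estimated correlation as well). Its members Abcg1 and Srebf1 differed by 0.07 and 0.12 over the 12 arrays and by 0.60 and 0.59 on slide 1, and 0 members passed over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Among Parkinson and Alzheimer disease genes (18 tested, median -0.07, mean 0.01, adjusted p 0.32) Bin1 rose 1.44-fold (0.40 on slide 1). Adjusted over the list alone 4 rose, Clu and Ncstn among them, and on slide 1 the median was 0.33 (adjusted p 0.0157 with slide as a fixed block, and 0.42 with an estimated correlation as well).

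In lipid and energy metabolism, Lss rose 1.97-fold (log2 difference 0.98 ± 0.17 SE, adjusted p 0.0135, 0.67 on slide 1) as the single member of 26 cholesterol synthesis genes past either adjustment (median -0.12, adjusted p 0.906). Fatty acid synthesis (median -0.19, adjusted p 0.48) and fatty acid oxidation (median -0.16, adjusted p 0.452) were not shifted, with 0 members past either adjustment and 4 and 2 at an unadjusted p under 0.05. Scd2 and Elovl1 differed by 0.09 and -0.35, and Angptl4 and Hadha by -0.30 and -0.24. In glycolysis and the hypoxia response (32 genes, median -0.21, camera adjusted p 0.144, fry adjusted p 0.028) the glycolytic enzymes Pgam1 and Tpi1 fell 1.40-fold and 1.56-fold and hexokinase Hk1 rose 1.89-fold (-0.25, -0.25 and 0.43 on slide 1). Of 32 members, 3 rose and 10 fell when adjusted over the list alone. Cytosolic ribosomal proteins were not shifted over the 12 arrays (68 genes, median -0.08, adjusted p 0.671), with Rplp0 at -0.09 and Rpl19 at -0.19 and 0 members past either adjustment (10 at an unadjusted p under 0.05). On slide 1 their median was 0.14, with 54 of 68 higher (adjusted p 0.0167 with slide as a fixed block, and 0.83 with an estimated correlation as well). Of the xenobiotic response, the glucuronosyltransferase Ugt1a6 rose 1.32-fold (log2 difference 0.40 ± 0.09 SE, adjusted p 0.0306, 0.38 on slide 1), the one call by either adjustment among 4 tested AhR targets, too few for a list test. Among 5 tested CAR and PXR targets (median -0.23, adjusted p 0.736) 0 passed over all genes, with 3 at an unadjusted p under 0.05. Adjusted over the list alone Alas1 was higher (log2 difference 0.68) and Abcb1b lower (-0.47), and Cyp2c7 differed by -0.55 (adjusted p 0.182).

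Of the 38 list genes given here as past the threshold over all genes, 8 stayed past it in all 12 fits that left out 1 array (Lss, Dbp, Loxl2, Myc, Ncam1, Psma5, Wdr43 and Gins2), and 22 did so in 4 fits or fewer. Pcna and Tpi1 passed in 1 of them, and Glra1, Fis1, Col1a1, Hk1, Nusap1 and Psmd14 in 2. With the GC trend removed 6 were lost (Irf1, B2m, Fis1, Abcc1, Psmd14 and Nolc1), and when slide was a fixed block the smallest adjusted p among the 38 was 0.0938. In all, camera with a preset correlation called 8 of 32 lists, 6 lower and 2 higher, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.397. With slide as a fixed block 10 lists were called, 6 higher and 4 lower, of which proteasome subunits and immediate early genes kept the call and direction they had over the 12 arrays. When that block and an estimated correlation were used together, the smallest adjusted p was 0.42. Across slides 2 and 3 alone, proteasome subunits and immediate early genes were not called (camera adjusted p 0.347 and 0.261). Slide 1 is part of the 12 arrays, so its calls are not an independent check of those over the 12. By fry, 10 lists passed for a shift in 1 direction, the 8 that camera called and, both lower, p53 targets and glycolysis. Its test for change in either direction passed 24 lists. Slide was not a term in fry, so a difference between slides could pass these tests as well. The 8 called lists kept their direction relative to the median of all genes under each of the 5 other scalings. That median was -0.08 as reported, -0.18 with median scaling and 0.17 with a normexp background and 75th percentile scaling.

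**Figure D3:**
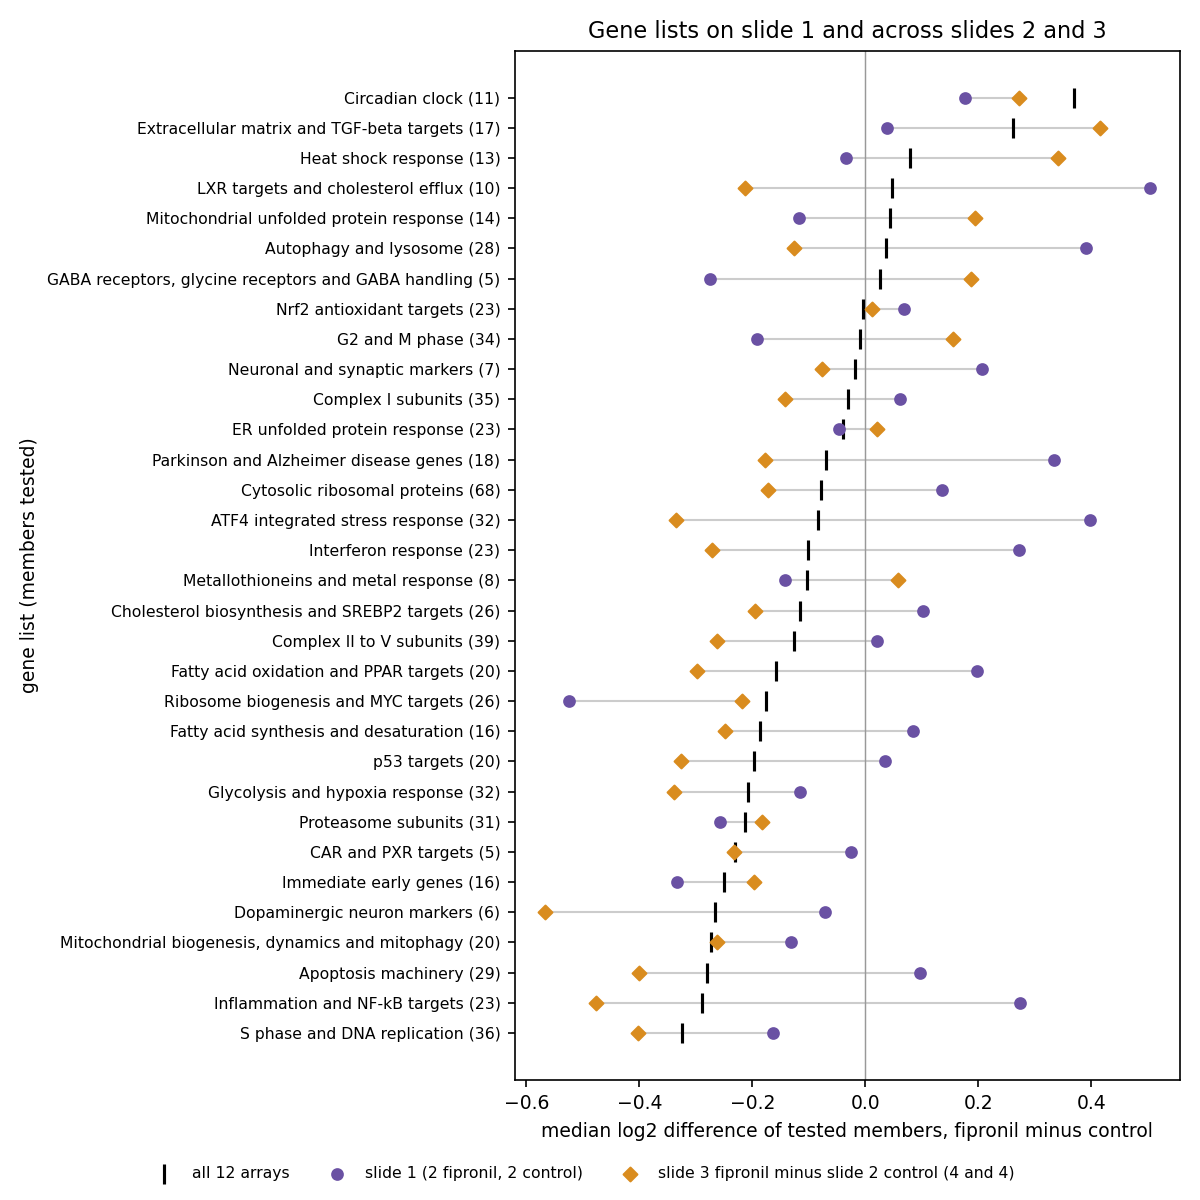
For each of the 32 tested lists, the median log2 difference of its members, fipronil minus control, is shown over all 12 arrays (bars), on slide 1 (circles, 2 fipronil and 2 control arrays) and between slide 3 fipronil and slide 2 control arrays (diamonds, 4 and 4). Proteasome subunits and immediate early genes lie below 0 in all 3, while ATF4 targets lie at 0.40 on slide 1 and at -0.34 across slides 2 and 3.

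Genes could also be compared between slides within a treatment, where fipronil does not differ. Between the 2 controls of slide 1 and the 4 of slide 2, 0 of 13542 genes passed in limma, with 3031 (22.4%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.164. Between the 2 fipronil arrays of slide 1 and the 4 of slide 3, 0 passed, with 2572 (19.0%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.065. With a normexp background and quantile normalization 404 genes passed in the fipronil arrays and 0 in the controls, the latter with 3167 at an unadjusted p under 0.05. Across slides 2 and 3, where slide and treatment cannot be told apart, 3044 genes differed between fipronil and control, and on slide 1 alone 0 did, with 2140 at an unadjusted p under 0.05.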

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

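The tests of probe GC content and the separate splits by slide were chosen only after the result was seen, and the other tests in this part before it.

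In 14 of 272 groups of 6 values (5.15%), the most extreme array stood apart from the others by Dixon's test at its 95% critical value, and chance alone gives about 5%. Control replicate 2 stood apart for Arg1 (log2 signal -0.63, the others -1.38 to -1.20), Bdnf (-3.17, others -4.25 to -3.87), Th (-1.93, others -1.40 to -1.16), Cnp (-3.38, others -2.56 to -2.19) and Nolc1 (3.16, others 2.49 to 2.66). Control replicate 5 did so for Lemd3 (-3.74, others -3.47 to -3.34), Rplp0 (8.52, others 7.98 to 8.17) and Col1a1 (-3.25, others -2.54 to -2.21). Control replicate 3 did so for Cox6a1 (1.37, others 6.59 to 6.95) and control replicate 7 for Stam (-4.27, others -3.93 to -3.79). Fipronil replicate 8 stood apart for Th (-1.06, others -2.27 to -1.86), Gadd45a (0.91, others 1.75 to 1.97) and the median of the S phase list (-0.13, others -0.39 to -0.31), and fipronil replicate 3 for Arg1 (-3.51, others -2.35 to -2.09).

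Fipronil minus control differences on slide 1 ran opposite to those across slides 2 and 3, with a correlation over genes, which are not independent replicates, of -0.24 (95% bootstrap interval -0.26 to -0.22). Of the genes with an unadjusted p under 0.05 in both, 318 differed in the same direction and 409 in opposite directions. Probe GC content as the whole source is argued against, since the correlation stayed at -0.16 (-0.18 to -0.14) with each array's GC trend removed. Weak signal on slide 3 is argued against too, by -0.21 (-0.24 to -0.18) in the 5300 brighter of the genes above background on every array. Fipronil replicate 8 alone may account for the sign, as the correlation was 0.046 (0.029 to 0.066) without it and -0.37 without fipronil replicate 7, and a slide difference and a biological difference between the fipronil samples remain open and untested.

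Signal on slide 3 was weaker than on slide 2, by -1.80 on the log2 scale at the 75th percentile. Spike-in probes, added in fixed amounts, fell as well, with a median of -1.68 (range -1.92 to -1.58) over the 4 probes well above background on all arrays. Less sample RNA relative to the spike-in is argued against by that value, since spike-ins would then have kept their level. Weaker labelling, hybridisation or scanning of every spot may be the source, as the change of the spike-ins differed from that of the sample probes by 0.11 (range -0.12 to 0.21). Which of these steps differed was not tested, and slide 3 holds fipronil samples alone.

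Lysosomal genes were higher with fipronil on slide 1, where the fixed list had a median log2 difference of 0.39, against -0.13 across slides 2 and 3. Probe GC content is argued against for slide 1, where the list's median stayed at 0.33 with the GC trend removed. The camera adjusted p was then 4.63e-05 with slide as a fixed block and the preset correlation. Without removal of the trend, the slide-blocked adjusted p was 0.42 with an estimated correlation. A rise of lysosomal genes with fipronil was tested on 40 further lysosomal genes outside the list, whose median relative to all genes was 0.35 (95% interval 0.29 to 0.56) on slide 1 and 0.21 (-0.13 to 0.34) across slides 2 and 3. Both intervals come from resampling the genes, which are not independent replicates, and do not measure the spread between arrays. Because the interval across slides 2 and 3 includes 0, and slide and treatment cannot be told apart there, the hypothesis of such a rise stays open.

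Chance can be excluded for the count of 678 changed genes only against splits that mix the slides. Of 100 splits of the 12 arrays into 6 and 6, 1 reached it, the real one, while the highest of the others gave 246 and 96 gave 0 (limma). The 5 other splits that keep slides 2 and 3 apart were not among the 100 drawn and were run separately. Of these 5, 3 gave more genes than the real one, up to 1591 for slide 2 with fipronil replicates 7 and 8 against slide 3 with control replicates 2 and 3. Against these splits the count does not stand out, so it cannot be told apart from a structure of the samples by slide, and the count with slide as a fixed block was 12. Chance cannot be excluded for the count of 8 shifted lists, which 43 of 100 splits reached, with 12 as the highest of the others.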

How the results depend on the processing

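The settings with the GC trend removed and the one without slide 3 were chosen only after the result was seen. For the cause of the changes below no test was made unless stated: the cause was not tested. The count of 678 changed genes lay between 585 and 965 under 9 settings: quantile normalization, median scaling, normexp with quantile normalization, the deposited values, the all-array filter, both probe choices, trend and robust eBayes, and removal of the GC trend. It was 6774 with normexp and the 75th percentile and 16313 of 36181 with no filter on dim probes, where the median of all genes was 0.17 and 0.55, against -0.08 as reported. It was 12 with slide as a fixed block, 21 with slide as a random block, 16 with the GC trend removed and slide blocked, 3044 on slides 2 and 3 alone and 2219 with array weights. It was 0 in limma in 4 fits: slide 1 only (2140 genes at an unadjusted p under 0.05), replicate block (2164), replicate block with slide block (2157) and without the 4 arrays of slide 3 (1863), fits with 2, 3, 2 and 6 residual degrees of freedom against 10. With 1 array left out it ranged from 228 to 2022, and 193 genes passed in each of the 12 fits. The balance of higher and lower genes changed too. It was 303 and 375 as reported, 376 and 301 with quantile normalization, and 150 and 435 with median scaling. With the GC trend removed it was 498 and 337, with normexp and the 75th percentile 5113 and 1661, and with no filter 15088 and 1225.

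The 8 shifted lists became 21 with no filter on dim probes, 5 with the replicate block, 2 with the replicate and slide blocks, 5 with array weights, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 24 by fry for change in either direction, and 4 to 10 with 1 array left out. Under the other settings between 6 and 12 were called. The count of genes differing between slides within a treatment rose from 0 to 3 in controls and 13669 in fipronil arrays with no filter on dim probes, and to 404 in fipronil arrays with normexp and quantile normalization.

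Direction here is camera's, relative to all other tested genes, and the median log2 difference under the alternative is in brackets. Among lists called either over the 12 arrays or under the alternative, these turned direction. With slide as a fixed block and on slide 1 alone these were apoptosis machinery (0.10), cytosolic ribosomal proteins (0.14), G2 and M phase (-0.19), inflammation and NF-kB targets (0.27) and interferon response (0.27). With the GC trend removed as well they were apoptosis (0.069), G2 and M phase (-0.22), inflammation (0.26) and interferon (0.23), and with the replicate block cytosolic ribosomal proteins (0.069). With no filter on dim probes 8 lists lay on the other side of the raised median of all genes: ATF4 targets (0.021), autophagy and lysosome (0.013), cholesterol biosynthesis (-0.12), circadian clock (0.40), complex I (-0.034), ER unfolded protein response (-0.040), G2 and M phase (-0.0038) and Nrf2 targets (0.042). With normexp and the 75th percentile complex I (-0.21) did so. A further 7 lists, called neither over the 12 arrays nor with slide as a fixed block, also turned camera's direction under that block. They were complexes II to V, dopaminergic markers, ER unfolded protein response, fatty acid oxidation, fatty acid synthesis, heat shock and p53 targets. The medians of dopaminergic markers (-0.27 over the 12 arrays, -0.07 with the block) and the ER unfolded protein response (-0.040 and -0.046) stayed below 0. Of the lists called with that block, ATF4 targets (-0.08 and 0.40) and Parkinson and Alzheimer disease genes (-0.07 and 0.33) had medians that crossed 0. For both, camera's direction stayed up.

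Among named genes past the threshold over the 12 arrays or under the alternative, these turned to rises with normexp and the 75th percentile: Nt5c1b (0.33), Trim21 (0.42), Slc26a4 (0.39), Lemd3 (0.39), Lrp12 (0.43), Stam (0.54), Ccdc103 (0.55), Bdnf (0.52), Glra1 (0.51), Cnp (0.28) and Mag (0.56). Nfkbiz became 0.11 there (adjusted p 0.492), below the median of all genes. Prc1 became -0.0048 with slide as a fixed block and on slide 1 alone, and -0.018 with the GC trend removed as well, a setting under which Irf1 became 0.069 and Abcc1 -0.072. Of 95 named genes, 20 turned with slide as a fixed block, Prc1 and 19 that passed in neither fit, among them Th (0.10), Cdkn1a (0.59), Bax (0.22), Ndufb8 (0.13), Hadha (0.44), Hspd1 (-0.30) and Flt1 (-0.17). Counted over the named genes and their alternatives, 2111 values kept direction and side of the threshold, 109 turned direction without passing in either fit, 738 kept direction but no longer passed, 51 newly passed in the same direction and 17 turned with a pass in at least 1 of the fits. For the lists these were 748, 90, 81, 48 and 24. Signal over background limits the genes with few arrays above it: 22 changed genes had no array of 1 treatment well above background.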

Other observations

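The test of a lysosomal gene program was chosen before the result was seen, and the genes named in this part were chosen after their values were seen.

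On the slide that holds both treatments, 12 genes passed with slide as a fixed block. The matrix link protein gene Hapln1 was lower with fipronil, with a log2 signal of -3.02 in the 2 controls and -5.96 in the 2 fipronil arrays. It stood well above background on 6 control arrays and 0 fipronil arrays, and its log2 fall was 2.01 against the background level. Tmem223 and Tfb2m, which encodes a mitochondrial transcription factor, were lower as well, with log2 differences of -1.71 and -1.38, and the clock regulator Ciart was lower by 1.33. Higher were Fmod, which encodes the matrix proteoglycan fibromodulin (2.65), Renbp (2.16), the lysosomal sulfatase Arsg (1.61 against the background level), the melanosome and lysosome glycoprotein Gpnmb (1.68), Gaa (1.59), Pyroxd2 (1.53), the ceramide synthase Cers1 (1.27) and the autophagy gene Tecpr1 (1.24). Their adjusted p ran from 0.00234 for Hapln1 to 0.0487 for Gpnmb and Tecpr1. Hapln1, Ciart, Fmod, Arsg and Pyroxd2 had 0 arrays of 1 treatment well above background on slide 1. For Ciart, Fmod and Pyroxd2 the background level left the measured values unchanged. Their differences therefore rest partly on values not well above background and are not bounds. Across slides 2 and 3 Gaa (0.88), Tecpr1 (0.56), Gpnmb (0.50), Tmem223 (-0.38) and Fmod (0.21) kept their direction, Tfb2m (-0.03) and Renbp (-0.02) lay near 0, and Ciart (1.76) and Cers1 (-0.64) lay on the other side of 0. No difference across slides 2 and 3 is given for Hapln1, Arsg and Pyroxd2, which stood well above background on 0, 0 and 1 of the 4 arrays of slide 3.

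With slide as a random block, 21 genes passed, among them the lysosomal peptidase Tpp1 (log2 difference 0.95 over the 12 arrays, 0.88 on slide 1), the synaptic protein gene Cplx2 (0.98 and 0.85) and the calcineurin regulator Rcan3 (1.01 and 0.87), which were higher. Lower were Ywhaz, of the 14-3-3 family (-0.87 and -0.74), the cell cycle subunit Cks1b (-0.79 and -0.67), the amino acid transporter Slc38a2 (-0.71 and -0.72) and the regulatory kinase subunit Prkar1b (-0.98 and -0.69).

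Of 50 further lysosomal genes outside the fixed list, 40 were tested over the 12 arrays, and 3 rose and 0 fell. The galactosidase Glb1 had a log2 difference of 0.49 ± 0.12 (SE), Scpep1 one of 0.53 ± 0.14 (SE) and Fnip2 one of 0.55 ± 0.14 (SE). Larger differences fell short of the threshold in limma for Nagpa, which was lower (-0.998, adjusted p 0.051), and Ctsz, which was higher (0.966, adjusted p 0.0655). Nagpa differed by -1.03 on slide 1 and -0.98 across slides 2 and 3, and Ctsz by 0.91 and 0.996. On slide 1, 35 of the 40 were higher, and across slides 2 and 3, 22 were.

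On slide 1, ATF4 targets with large differences were the asparagine synthetase gene Asns (1.70), Nupr1 (1.45), Pycr1 (1.23) and Pck2 (1.21), whose differences across slides 2 and 3 were 0.10, -0.15, -0.03 and -0.33. The lipid transfer gene Pltp differed by 1.07 and -0.17, and the lysosomal cholesterol carrier Npc2 by 0.82 and -0.23. The interferon target Usp18 differed by 1.24 and -0.25. The mitotic genes Cenpf and Ttk differed by -1.35 and -1.18 on slide 1 and by 1.33 and 0.13 across slides 2 and 3.

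The first principal component of the 13542 genes held 39.6% of the variance and the second 17.8%. On the first, fipronil replicate 8 lay at 46.9, near control replicates 5 and 6 at 42.0 and 40.6, while fipronil replicates 1 and 2 lay at -47.7 and -42.0. The component's loadings correlated with probe GC content at 0.35 over genes.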
